A study of Homo sapiens with 3 samples.

How the data were processed

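RNA was measured in HCT116, a human colorectal carcinoma cell line, in 3 libraries, 1 for each treatment label: Mock, GPS167 and GPS192. The labels' treatment protocol names DMSO, the solvent, beside GPS167 and GPS192. Doses, treatment times and the structures of the compounds are not given in the sources used here. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy column kit and poly(A) RNA was made into Illumina libraries. Whether the libraries kept the strand of the RNA is not given in the sources used here, so reads from a gene and from an overlapping gene on the other strand may have been mixed.

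Per the submitters' processing notes, the tools were Trimmomatic (read trimming), Bowtie2 (alignment) and RSEM (estimates of transcript abundance), on the genome build GRCh38. Their versions, order and settings are not given in the sources used here. The authors deposited 1 TPM value (transcript abundance scaled to a fixed sum per library) per gene and library, the sum over the Ensembl transcripts listed for that gene. The authors also deposited a percent spliced in (PSI) per splicing event and library. It is the TPM of the transcripts that hold the long form, taken as a percent of the TPM of the long and short forms together. The summed long and short isoform signal of each event, in TPM, was deposited by the authors beside it. These PSI values therefore come from transcript abundances assigned by a model, not from reads counted across splice junctions. An event whose transcripts are rare has a PSI that rests on very little signal. The forms of an event can also be a small part of the gene's transcripts, so a PSI is not a share of all the gene's RNA. Multiplying each of the 89588 PSI values by its isoform signal gave a whole hundredth of a TPM, within a tolerance of 1e-06 TPM, in 89588 cases. The authors' log2 ratios were not used and were recomputed from the deposited TPM values.

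The expression table held 26861 genes and 31706 events stood in the splicing table. Lines without values, 2 in the expression table and 7 in the splicing table, were left out. TPM is scaled to the same sum in each library and keeps no record of sequencing depth, so depth is unknown and no counting interval or detection floor is given. Each treatment has 1 library, so no difference has a replicate check, and no p-value, standard error or adjusted p was computed. Differences between libraries can come from the treatment, the culture or the library, and they are given as sizes.

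Genes with a mean of at least 1 TPM over the 3 libraries (13921 genes) were compared as log2(TPM + 1). A gene was counted as higher or lower at a difference of 2-fold or more on that scale, which understates differences of genes at low levels. Events with a PSI in all 3 libraries (28088 events) whose host gene had a mean of at least 1 TPM (24173 events) were compared as differences of PSI in percentage points and counted at 20 points or more. Because many of the events so counted had isoforms under 1 TPM, the counts are also given for events whose long and short isoforms summed to more than 10 TPM in both compared libraries, the limit of the authors' own flag; this set was chosen after the data were seen.

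A set of 28 gene lists for expression and 8 for splicing was fixed before the data were examined, as were the comparisons, thresholds and alternatives, except those said to be added. The list medians of 25 expression lists with at least 5 measured members were placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart when its percentile lay outside the central 95% of these lists. The share of a list's genes with an event past 20 points was placed in the same way among random lists matched on the number of events. Such percentiles describe these libraries and are not tests of the treatments. Some genes belong to several lists. The splicing list of reported SRSF10 targets was written from general knowledge, not from these libraries.

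Both compounds were compared with the same Mock library, which makes their differences alike even without any effect. Correlation, covariance and overlap were therefore set beside 100 simulated sets of unchanged libraries that share 1 control, with noise drawn from the difference between the GPS167 and GPS192 libraries in bins of mean expression. That noise also holds any real difference between the compounds. The overlap of independent lists (n1 × n2 / N) is given too.

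The text names, for each comparison with Mock, the 10 genes with the highest and the 10 with the lowest log2 difference among genes with a mean of at least 5 TPM, and the 5 at each end for GPS167 against GPS192. In each list it names up to 4 measured members with the largest mean difference from Mock. CLK1 to CLK4, SRSF10, MDM2 and CDKN1A were always to be named, and genes without a symbol were passed over. Not every gene that the rule picked is printed. For splicing, the rule took the 10 events with the largest PSI difference per comparison, 1 per gene, from host genes with a mean of at least 5 TPM, and up to 4 genes per list. Events with isoforms above 10 TPM were named by the same rule, applied after the data were seen.

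Gene positions and types were taken from GENCODE release 29, which is on GRCh38, the build named by the submitters. Of the 70436 Ensembl transcript identifiers in both tables, 64401 were found there, and 26739 of the 26861 genes had a position. Near-identical genes, such as H2BFS and HIST1H2BK, HIST2H2AA4 and its copy HIST2H2AA3, HSPA1A and HSPA1B, or HBA2 and HBA1, share reads, so the values of single members are uncertain.

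Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots. The counting of genes was tested on libraries simulated from the genes' mean TPM over the 3 libraries. Noise had an SD of 0.15 log2 units, and 200 changed genes were drawn from those with a mean of at least 10 TPM. In the set simulated for GPS167 against Mock, it recovered 95 of 100 genes at a log2 difference of 1.5. At 2.5 it recovered 100 of 100, with 0 false calls among 13921 genes. Noise this small lies far inside the 2-fold threshold. The test therefore checks the calculation and does not measure errors in the real libraries. The alternatives tried for expression were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 TPM, fold thresholds of 1.5 and 3, median ratio scaling of the libraries, and random lists not matched on expression. For splicing they were differences of 10 and 30 points, no filter on the host gene or a mean of at least 10 TPM, and 1 event per gene. That event was the one with the largest difference from Mock in either compound. Added after the data were seen were both compared libraries above 10 TPM, isoforms above 10 TPM, and leaving out 322 genes of short or non-polyadenylated RNA with rescaled TPM.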

Results

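Poly(A) RNA of HCT116 colorectal carcinoma cells was profiled after Mock treatment or treatment with GPS167 or GPS192, compounds that the series' title places among inhibitors of the CDC2-like kinases (CLKs), which phosphorylate the serine- and arginine-rich (SR) splicing factors. The design asked how each compound bears on alternative splicing and gene expression. There was 1 library per treatment and no replicate, so each value below is that of a single library, and depth is unknown because the deposited values are TPM. At least 1 TPM was reached by 13688 genes in the Mock library, 13843 in the GPS167 library and 14096 in the GPS192 library, while 3568, 3207 and 1617 genes were listed at 0. Mitochondrial genes held 16.4%, 17.2% and 16.4% of the TPM. Short or non-polyadenylated RNA genes held 2.56%, 0.590% and 2.09%, of which the 5.8S ribosomal RNA gene RNA5-8S5 made up most in the Mock library; it stood at 18096, 0 and 10071 TPM.

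In the GPS167 library, p53 target genes, immediate early genes, histone genes and genes of DNA replication were higher than in the Mock library, and genes of the G2 and M phases were lower. Of the 13921 genes compared, 643 were at least 2-fold higher and 296 at least 2-fold lower in the GPS167 library. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cyclin-dependent kinase inhibitor p21, stood at 261 TPM in the Mock library and 1652 TPM in the GPS167 library. MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686), the ubiquitin ligase that degrades p53, stood at 52.3 and 229 TPM.

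Of 38 measured p53 targets, 29 were at least 2-fold higher in the GPS167 library than in Mock and 0 were at least 2-fold lower. Their median log2 difference was 1.39, against -0.10 to 0.23 for the central 95% of expression-matched random lists. The members with the largest differences were the polo-like kinase gene PLK2 (9.96 and 170 TPM), CDKN1A, the antiproliferative gene BTG2 (28.3 and 165 TPM) and the metabolic regulator TIGAR (5.15 and 27.2 TPM). Among 22 p53 regulators the median was 0.02, inside the random range of -0.16 to 0.29, and it lay below 0 under median ratio scaling and without short RNA genes. There, MDM2, the phosphatase gene PPM1D (20.2 and 82.9 TPM), ING1 (18.3 and 41.4 TPM) and RCHY1 (23.8 and 50.5 TPM) stood above the others. ING1 and RCHY1 were under 2-fold with a pseudocount of 5.

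Cell cycle genes separated by phase in the GPS167 library. Of 36 G2/M genes, 15 were at least 2-fold lower than in Mock and 35 were below 0, with a median of -0.93 (random range -0.11 to 0.24). Among them were the mitotic kinase genes AURKB (ENSG00000178999, chromosome 17, 8204733 to 8210600; 57.9 and 20.6 TPM) and NEK2 (37.2 and 9.56 TPM), the CDK1-activating phosphatase gene CDC25C (16.1 and 3.89 TPM) and the centromeric histone gene CENPA (18.1 and 6.18 TPM). Of 36 G1/S and replication genes, 34 were above 0 and 5 at least 2-fold higher, with a median of 0.64 (random range -0.12 to 0.23). The DNA polymerase clamp gene PCNA, which is also a p53 target, stood at 149 and 461 TPM, the phosphatase gene CDC25A at 4.35 and 18.5 TPM and the replication helicase gene GINS3 at 6.89 and 25.1 TPM. RRM2, a subunit of ribonucleotide reductase, went the other way, at 85.9 and 61.5 TPM.

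Replication-dependent histone genes had a median log2 difference of 2.62 between the GPS167 and Mock libraries, with 10 of 12 measured members at least 2-fold higher (random range -0.24 to 0.34). HIST1H2BK stood at 23.3 TPM in Mock and 792 TPM in GPS167, HIST1H2BC at 2.20 and 55.8 TPM, HIST1H2BD at 15.5 and 243 TPM and HIST2H2BE at 5.12 and 81.6 TPM. Histone copies share reads, so the level of each member is uncertain. Replication-dependent histone mRNAs mostly lack a poly(A) tail, and these libraries were made from poly(A) RNA.

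Immediate early genes, which respond to growth factors and stress within minutes to hours, had a median of 1.61, with 18 of 28 at least 2-fold higher in the GPS167 library (random range -0.14 to 0.25). The transcription factor genes EGR1 and JUN stood at 25.5 and 429 TPM and at 10.3 and 78.9 TPM, and the matricellular genes CTGF and CYR61 at 0.85 and 56.7 TPM and at 5.90 and 96.8 TPM. NF-kB targets had a median of 1.07 (0.67 with a mean of at least 10 TPM), with 8 of 16 at least 2-fold higher (random range -0.20 to 0.31). The chemokine genes CXCL3 (0.83 and 31.4 TPM) and CXCL1 (0.59 and 9.52 TPM) were among them. Heat shock genes had a median of 0.80, with 5 of 13 at least 2-fold higher (random range -0.23 to 0.32), including HSPA1B (73.7 and 324 TPM), HSPH1 (34.1 and 95.5 TPM) and HSPA4L (11.5 and 32.8 TPM). HSPA1A, a near-identical copy of HSPA1B, stood at 0.92 and 2.77 TPM.

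Core spliceosome genes had a small upward median of 0.43 in GPS167 against Mock, with 36 of 37 above 0 and 0 at least 2-fold higher (random range -0.10 to 0.23). SF3B4 stood at 28.3 and 51.8 TPM, PRPF4 at 32.3 and 56.9 TPM, SF3A3 at 40.8 and 66.7 TPM and U2AF2 at 97.0 and 167 TPM. SR and SR-like protein genes had a median of 0.25 (random range -0.22 to 0.33), with the largest differences in SRSF8 (12.1 and 23.4 TPM), SRSF2 (176 and 355 TPM), TRA2B (146 and 270 TPM) and SRSF3 (145 and 233 TPM). SRSF2 passed 2-fold, but not with a pseudocount of 5 or under median ratio scaling. SRSF10 (ENSG00000188529, chromosome 1) was at 98.1 TPM in Mock and 117 TPM in GPS167. SR protein kinase genes had a median of 0.34, at the edge of the random range of -0.21 to 0.34 (percentile 97.4); it stood outside the central 95% with a pseudocount of 0.1, with a mean of at least 10 TPM and among unmatched random lists. CLK1 was at 60.6 and 101 TPM, CLK2 at 30.3 and 39.7 TPM, CLK3 at 32.0 and 44.2 TPM and CLK4 at 9.41 and 16.7 TPM, and HIPK1 and PRPF4B had log2 differences of 0.64 each. Genes of the hnRNP splicing factors had a median of 0.12, inside the random range of -0.15 to 0.24; PTBP2 stood at 5.78 and 13.1 TPM, HNRNPAB at 143 and 233 TPM, HNRNPC at 1374 and 1011 TPM and PCBP2 at 443 and 328 TPM.

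Apoptosis regulators had a median of 0.13 in GPS167 against Mock, inside the random range of -0.12 to 0.24, with 8 of 36 at least 2-fold higher. The p53 targets PMAIP1 (67.0 and 213 TPM), BAX (93.5 and 209 TPM) and FAS (10.6 and 27.0 TPM) were among these 8, as was the caspase regulator BIRC3 (7.54 and 21.6 TPM). DNA damage response and repair genes had a median of 0.22, at percentile 97.7 of the random lists, which became 88.3 with a mean of at least 10 TPM. RAD51C stood at 42.5 and 72.5 TPM, PALB2 at 5.88 and 11.6 TPM and FANCI at 32.0 and 22.0 TPM.

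Besides CTGF, CXCL3 and the histone genes HIST1H2BK and HIST1H2BC, the highest differences of GPS167 from Mock among genes with a mean of at least 5 TPM were those of the histone genes HIST1H2BO (0.11 and 51.3 TPM), H2BFS (21.4 and 764 TPM), HIST1H2BJ (0.21 and 28.7 TPM), HIST1H2AK (listed at 0 and at 19.4 TPM) and HIST2H2AA4 (20.7 and 409 TPM). PIGY.ext1, which lies inside PIGY in the annotation, was listed at 0 in Mock and at 19.1 TPM in GPS167. At the low end, RNA5-8S5, the small nucleolar RNA genes SNORA70 (32.5 TPM in Mock) and SNORA46 (21.7 TPM), the U1-like gene RNU1-106P (10.1 TPM) and TTC28-AS1_2 (2.78 TPM) were listed at 0 in GPS167. The remaining genes at that end were IFITM1, an interferon-induced membrane protein gene (25.7 and 3.15 TPM), HMSD (5.71 and 0.16 TPM), PCK2, the mitochondrial phosphoenolpyruvate carboxykinase gene (59.6 and 12.5 TPM), CYP24A1, which inactivates vitamin D (190 and 42.9 TPM), and the globin gene HBA2 (11.7 and 2.19 TPM). Leaving out short and non-polyadenylated RNA genes brought in C6orf223 (11.1 and 2.22 TPM), ETV1 (18.0 and 4.08 TPM), C6orf141 (19.6 and 4.55 TPM), IGF2BP3 (129 and 34.4 TPM) and NEK2.

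**Figure D1:**
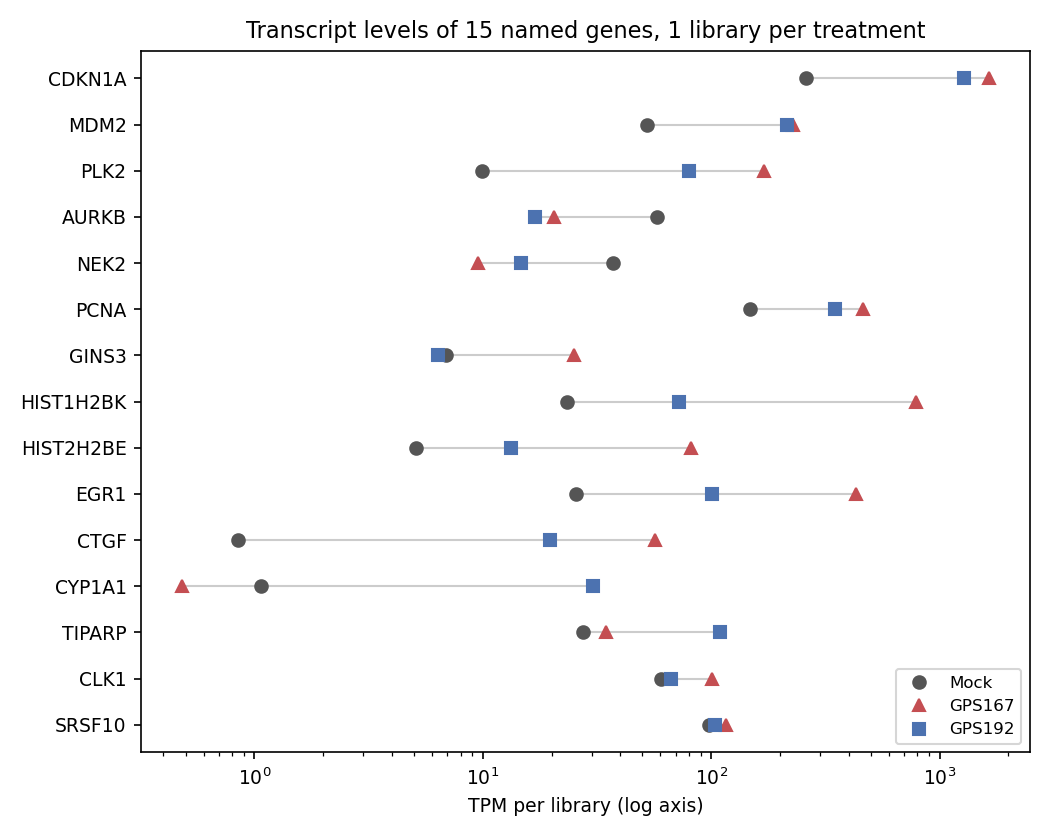
TPM (log axis) of named genes in the Mock, GPS167 and GPS192 libraries, 1 point per library, joined by a line per gene. CDKN1A stood at 261 TPM in Mock and at 1652 and 1275 TPM in the treated libraries, HIST1H2BK reached 792 TPM in the GPS167 library, and CYP1A1 was above 1.07 TPM only in the GPS192 library, at 30.3 TPM.

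In the GPS192 library, p53 targets were again higher and G2/M genes lower than in Mock, while the replication list lay slightly below 0 and targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, were higher. At least 2-fold higher were 340 of the 13921 genes, and 120 were at least 2-fold lower. Under median ratio scaling the counts were 282 and 166, a share of higher genes of 62.9% against 73.9%. CDKN1A stood at 261 TPM in Mock and 1275 TPM in GPS192 and MDM2 at 52.3 and 214 TPM.

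Of the 38 p53 targets, 29 were at least 2-fold higher in GPS192 than in Mock, with a median of 1.32 (random range -0.03 to 0.21). PLK2 reached 79.7 TPM, BTG2 104 TPM and TIGAR 22.4 TPM. The p53 regulator list had a median of 0.14 (random range -0.07 to 0.25), with MDM2 and PPM1D (77.4 TPM in GPS192) at least 2-fold higher. Of 36 G2/M genes, 15 were at least 2-fold lower and 36 were below 0, with a median of -0.96 (random range -0.03 to 0.23); AURKB was at 16.9 TPM, NEK2 at 14.8 TPM, CDC25C at 5.39 TPM and CENPA at 6.06 TPM. The G1/S and replication list had a median of -0.13, below the random range of -0.04 to 0.22. Within it PCNA was at 349 TPM, CDC25A at 7.75 TPM, GINS3 at 6.37 TPM and RRM2 at 38.6 TPM.

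The aryl hydrocarbon receptor list had a median of 1.45 in GPS192 against Mock, with 4 of 7 measured members at least 2-fold higher (random range -0.21 to 0.38). With a mean of at least 10 TPM the median was 0.56; that filter leaves out CYP1B1 and AHRR, the latter (3.50 and 11.3 TPM) named here after its values were seen. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610), a cytochrome P450 gene classically induced through this receptor, stood at 1.07 TPM in Mock and 30.3 TPM in GPS192. The related gene CYP1B1 stood at 0.67 and 4.32 TPM and TIPARP, which encodes a repressor of the receptor, at 27.6 and 110 TPM. CYP1B1 was under 2-fold with a pseudocount of 5. NQO1, a quinone reductase gene, was at 773 and 594 TPM.

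Immediate early genes had a median of 0.66 in GPS192 against Mock, with 12 of 28 at least 2-fold higher (random range -0.06 to 0.22). CTGF stood at 19.8 TPM, CYR61 at 53.9 TPM, EGR1 at 101 TPM and JUN at 50.4 TPM in the GPS192 library. NF-kB targets had a median of 0.91 (0.48 with a mean of at least 10 TPM), with 8 of 16 at least 2-fold higher (random range -0.11 to 0.28), among them CXCL8 (1.26 and 23.4 TPM), CCL20 (0.06 and 9.82 TPM) and CXCL1 (0.59 and 9.37 TPM). Heat shock genes had a median of 0.94, with 6 of 13 at least 2-fold higher (random range -0.14 to 0.25); HSPA1B was at 261 TPM, HSPH1 at 95.1 TPM and HSPA4L at 28.3 TPM. Histone genes had a median of 0.77, with 5 of 12 at least 2-fold higher (random range -0.14 to 0.32) and HIST1H2BK at 72.3 TPM. Apoptosis regulators had a median of 0.30, above the random range of -0.03 to 0.22, with 4 of 36 at least 2-fold higher: FAS (42.2 TPM), BIRC3 (28.1 TPM), BAX (233 TPM) and PMAIP1 (142 TPM, under 2-fold with median ratio scaling).

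Splicing factor genes stood closer to Mock in the GPS192 library. Core spliceosome genes had a median of 0.22 (random range -0.05 to 0.20, percentile 99), which became percentile 97.45 among unmatched random lists; 34 of 37 were above 0, and SF3B4 was at 44.1 TPM. SR protein kinase genes had a median of 0.16, with CLK1 at 67.0 TPM, CLK2 at 30.6 TPM, CLK3 at 39.4 TPM and CLK4 at 13.4 TPM. SR and SR-like protein genes had a median of 0.08, with SRSF2 at 193 TPM and SRSF10 at 104 TPM. Genes of hnRNP proteins had a median of -0.03, with HNRNPC at 949 TPM. Each of these last 3 medians lay inside its random range; the SR list median, SRSF10 and CLK2 took the other sign under median ratio scaling. DNA damage response and repair genes had a median of 0.01 (percentile 7.63), below 0 under median ratio scaling and without short RNA genes, with FANCI at 16.6 TPM.

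Apart from CTGF, CYP1A1, CXCL8, CYR61 and PLK2, the genes furthest above Mock in the GPS192 library were the U1 variant gene RNVU1-6 (listed at 0 in Mock and GPS167 and at 24.8 TPM in GPS192), PIGY.ext1 (listed at 0 and at 15.6 TPM), the keratin-associated gene KRTAP2-3 (3.91 and 60.1 TPM), TCL6 (1.83 and 21.5 TPM) and the small nucleolar RNA gene SNORD3A (2.95 and 27.8 TPM). Without short and non-polyadenylated RNA genes, GALNT5 (7.45 and 56.3 TPM) and CXCL1 joined them. At the low end, SNORA70 and SNORA46 were listed at 0, and PCK2 was at 11.97 TPM. That end further held AURKB, PHGDH (105 and 29.9 TPM) and ASNS (305 and 93.8 TPM), enzymes of serine and asparagine synthesis, the cystine transporter gene SLC7A11 (29.9 and 8.69 TPM), the RNA-binding protein gene IGF2BP3 (129 and 39.6 TPM), PRR11 (57.8 and 17.7 TPM) and the nuclear receptor gene NR2F1 (102.09 and 32.3 TPM). PSAT1 (218 and 70.6 TPM) and ETV1 (18.0 and 5.26 TPM) followed when short RNA genes were left out.

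**Figure D2:**
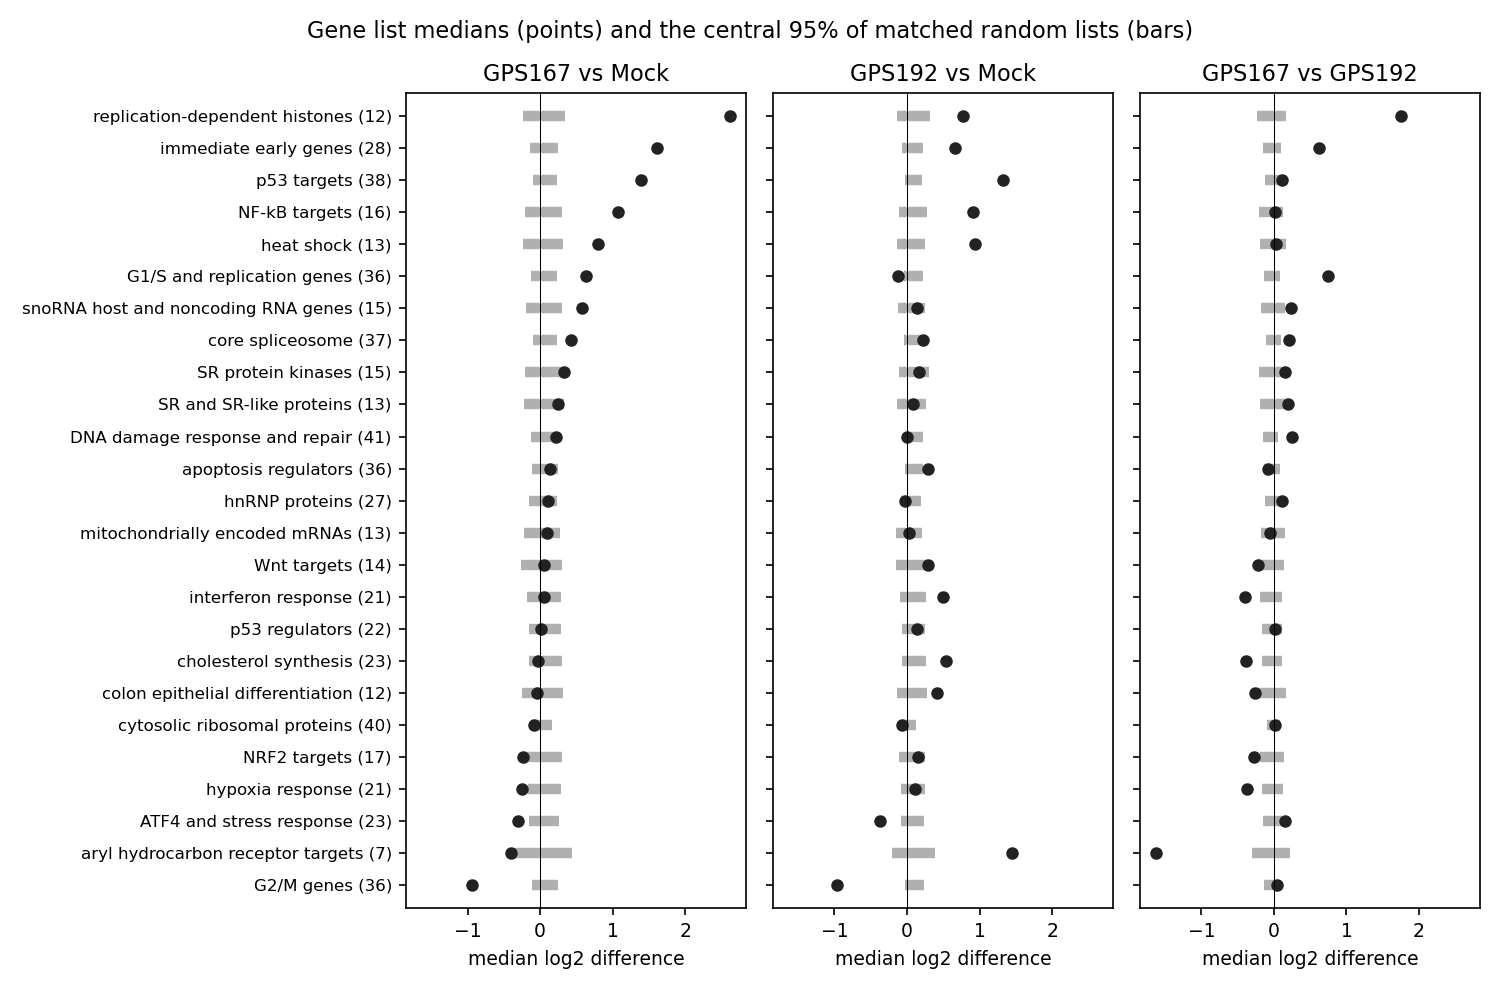
Median log2 difference of 25 gene lists (points; measured members in parentheses) in the 3 comparisons, with grey bars for the central 95% of medians of 10000 random lists of the same size matched on mean expression. The p53 target list lay at 1.39 and 1.32 in the comparisons with Mock and the G2/M list at -0.93 and -0.96, while the aryl hydrocarbon receptor list lay at -0.40 for GPS167 and 1.45 for GPS192.

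Set directly against each other, the compounds' libraries differed most, by list medians, in histone genes and replication genes, higher with GPS167, and in aryl hydrocarbon receptor targets, higher with GPS192. At least 2-fold higher in the GPS167 library were 205 genes, and 117 were at least 2-fold lower. With a mean of at least 10 TPM the counts were 91 and 27. Doses and times are not in the labels, so whether these were matched between the compounds is unknown. The p53 target list had a median of 0.10 (random range -0.13 to 0.08), with 37 of 38 members within 2-fold, and the G2/M list had a median of 0.05 (random range -0.14 to 0.08; 0.11 and outside the central 95% with a mean of at least 10 TPM), with 35 of 36 within 2-fold.

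Replication-dependent histone genes had a median difference of 1.75 between GPS167 and GPS192, with 10 of 12 members at least 2-fold higher in GPS167 (random range -0.23 to 0.17). The 5 genes furthest above GPS192, among those with a mean of at least 5 TPM, were histone genes, not all of them members of this list. HIST1H2BO stood at 51.3 TPM in GPS167 and 1.74 TPM in GPS192, H2BFS at 764 and 55.9 TPM, HIST1H2BK at 792 and 72.3 TPM, HIST1H3D at 22.4 and 1.43 TPM and HIST1H2AK at 19.4 and 1.25 TPM. All 36 members of the G1/S and replication list were higher in GPS167, with a median of 0.74 (random range -0.14 to 0.08), and 6 of them, such as GINS3 and CDC25A, were at least 2-fold higher. CDC25A was under 2-fold with a pseudocount of 5. Immediate early genes had a median of 0.63, with 8 of 28 at least 2-fold higher in GPS167, EGR1 among them.

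Aryl hydrocarbon receptor targets had a median of -1.63 in GPS167 against GPS192, with 5 of 7 at least 2-fold lower in GPS167 (random range -0.30 to 0.23). Part of this gap lay below Mock, since the list median of GPS167 against Mock was -0.40, under its random range of -0.35 to 0.44. CYP1A1 stood at 0.48 TPM in GPS167 and 30.3 TPM in GPS192, TIPARP at 34.7 and 110 TPM, CYP1B1 at 0.40 and 4.32 TPM and NQO1 at 267 and 594 TPM. At the same end of the comparison stood RNA5-8S5, TTC28-AS1_2 (0 and 26.4 TPM), RNVU1-6 and HMSD (0.16 and 14.1 TPM). Without short RNA genes, the water channel gene AQP3 (5.87 and 33.6 TPM), CXCL8 (4.18 and 23.4 TPM) and HBA2 (2.19 and 11.4 TPM) also appeared there. NF-kB targets had a median of 0.01 (below 0 without short RNA genes) but went both ways, with CXCL3 at 31.4 and 6.65 TPM and CCL20 at 1.04 and 9.82 TPM.

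Lists of splicing genes were slightly higher in GPS167 than in GPS192. The core spliceosome list had a median of 0.21 (random range -0.12 to 0.09), the SR and SR-like list 0.19 (random range -0.20 to 0.16), the SR protein kinase list 0.16 (random range -0.20 to 0.15) and the hnRNP list 0.11 (random range -0.13 to 0.11). The kinase and hnRNP lists fell inside the central 95% with a mean of at least 10 TPM. DNA damage response and repair genes had a median of 0.25 (random range -0.15 to 0.06). Heat shock genes had a median of 0.03, apoptosis regulators -0.08 and p53 regulators 0.02 (below 0 without short RNA genes), each inside its random range.

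Across the 13921 genes, the log2 differences of GPS167 and GPS192 from Mock had a Pearson correlation of 0.69 and a Spearman correlation of 0.73. Unchanged libraries that share a control gave a simulated Pearson correlation of 0.50 on average and at most 0.585. The covariance was 0.181 against 0.0923 in the simulation. In all, 192 genes were at least 2-fold higher in both, against 15.7 for independent lists and 62.9 (at most 88) in the simulation, and 78 were at least 2-fold lower in both, against 2.55 and 61.8 (at most 85). Lower in both were 111 genes under median ratio scaling (simulated at most 81), 78 without short RNA genes (at most 69) and 41 with a mean of at least 10 TPM (at most 38), each above the simulation. HMSD and the short RNA genes TTC28-AS1_2 and ENSG00000274630 (2.39 TPM in Mock, 0 in GPS167 and 52.4 in GPS192), named here after their values were seen, were at least 2-fold apart from Mock in opposite directions; with a pseudocount of 5, HMSD in GPS192 and TTC28-AS1_2 in GPS167 were under 2-fold. The single Mock library cannot be split, so part of the excess may come from the shared control, and genes are not independent replicates.

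**Figure D3:**
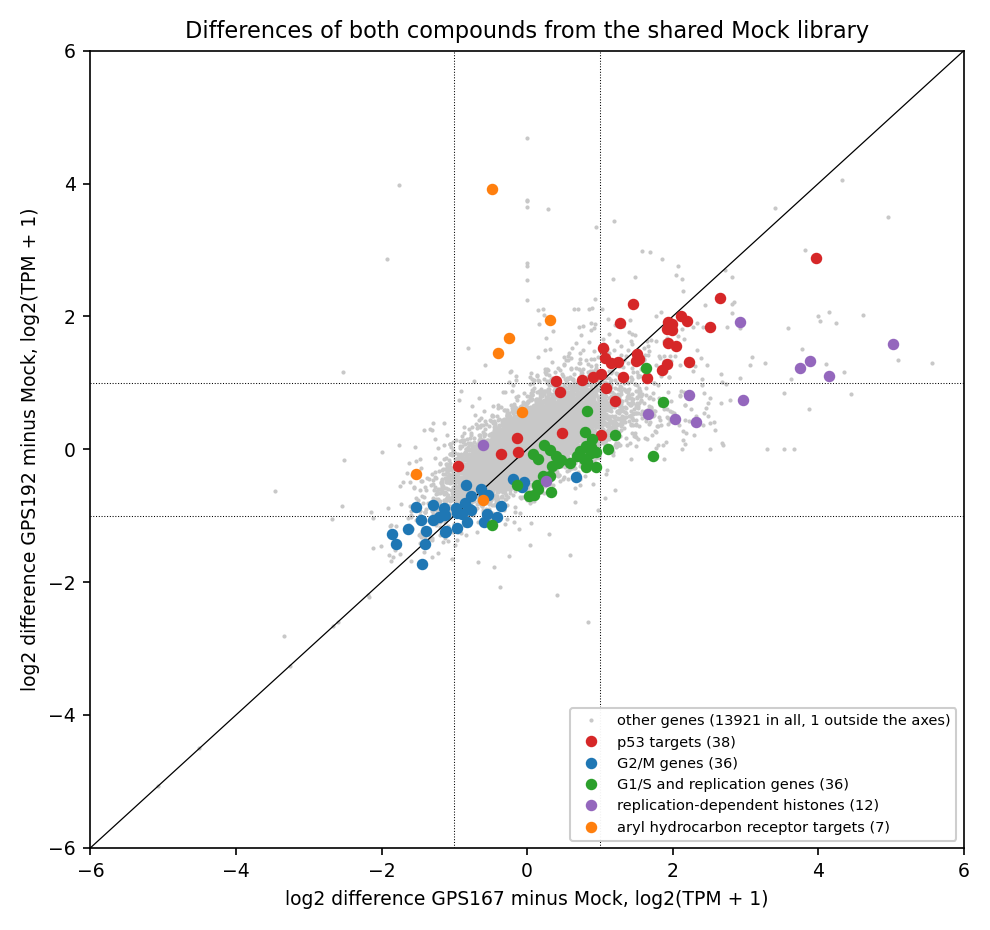
Log2 differences from the Mock library, on log2(TPM + 1), of GPS167 (x axis) and GPS192 (y axis) for 13921 genes (grey points, 1 outside the axes), with members of 5 lists in colour; dotted lines mark 2-fold and the solid line equal differences. The p53 targets and G2/M genes lie along the line, whereas replication genes and 11 of 12 histone genes lie below it and aryl hydrocarbon receptor targets mostly above it.

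Splicing events with lower PSI, that is with less of the long form, outnumbered those with higher PSI in the GPS167 library, most clearly for skipped exons. Of 24173 events, 738 had a PSI at least 20 points higher in GPS167 than in Mock and 986 a PSI at least 20 points lower, in 1063 genes. Of these 1724 events, 868 had isoforms under 1 TPM in a compared library. Among 11436 events with isoforms above 10 TPM in both libraries, 38 were higher and 90 lower, in 106 genes. Single exon skipping gave 43 of these 128 events, 33 of them with lower PSI, that is more skipping; multiple exon skipping gave 18, 15 of them lower, and intron retention 27, 14 of them lower and 13 higher. Over all events the counts higher and lower were 178 and 294 for single exon skipping, 98 and 182 for multiple exon skipping and 77 and 82 for intron retention.

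The 10 events furthest apart between GPS167 and Mock with isoforms above 10 TPM were as follows. In CPSF6, a cleavage and polyadenylation factor gene, the long form between 69251142 and 69262468 on chromosome 12, which holds coding exons, was at 97.52% PSI in Mock and 45.6% in GPS167. RAN, the nuclear transport GTPase gene, was at 100% and 52.7% between 130872127 and 130875654 on chromosome 12, and RBM42 at 92.0% and 46.2% between 35631197 and 35637249 on chromosome 19. In SLK a coding exon of 93 nt (chromosome 10, 104010816 to 104010908) was included at 80.7% and 34.9%. WRAP53 retained an untranslated or noncoding intron of 86 nt (chromosome 17, 7688562 to 7688647) at 12.2% and 59.2%. The noncoding snoRNA host genes SNHG1 (90.8% and 45.1%) and SNHG8 (78.1% and 34.2%) retained introns less in GPS167. RNF220 was at 40.8% and 86.4%, MAGEA2 at 100% and 57.1%, and PTMA at 35.0% and 77.1% for a segment of 2 nt. Some of these events covered a small part of their gene's signal. PTMA isoforms were at 11.7 and 11.9 TPM against a gene mean of 2167 TPM over the libraries. RAN isoforms were at 46.95 and 97.75 TPM against 563 TPM. Over all events regardless of isoform level, 34 were tied at a difference of 100 points. The 10 that the rule took from these ties (in CMTM3, LARP4, PLIN2, TBC1D22A, ZNF268, HOXB3, MSRB1, CPSF3L, MDM2 and EPB41L2) had isoforms of at most 0.71 TPM.

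The GPS192 library had fewer differing events than the GPS167 library. At least 20 points higher than in Mock were 636 events and at least 20 points lower 774, in 889 genes; 755 of the 1410 events had isoforms under 1 TPM in a compared library. Among 11688 events with isoforms above 10 TPM, 15 were higher and 36 lower, in 46 genes. Single exon skipping gave 16 events, 14 of them lower, multiple exon skipping 12, all 12 lower, and intron retention 6, all 6 higher. Over all events these classes were less one-sided, at 142 higher and 246 lower, 108 and 159, and 59 and 39; at 10 points intron retention was at 185 and 191.

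Coding exons were included less in several genes of the GPS192 library. A 119-nt exon of the anti-apoptotic gene HAX1 (chromosome 1, 154273480 to 154273598) was at 100% in Mock, 56.7% in GPS167 and 44.4% in GPS192. A 53-nt exon of ARPP19 (chromosome 15, 52568848 to 52568900) was at 36.7% in Mock and 0% in both treated libraries, and a 142-nt exon of BSCL2 (chromosome 11, 62691280 to 62691421) at 75.8%, 37.8% and 43.8%. Exon groups of TMPO (57.9%, 33.8% and 24.8%) and of the histidyl-tRNA synthetase gene HARS (76.0%, 51.9% and 44.7%) were skipped more in both treated libraries. Events of other kinds were also among those furthest apart. An untranslated or noncoding exon of FXR1 (94 nt) was at 70.5%, 59.3% and 37.9%. An alternative 3-prime event of RPS20 was at 79.6%, 44.9% and 44.6%. An alternative 5-prime and 3-prime event of ASXL1 was higher in both treated libraries, at 38.3%, 68.0% and 69.8%. Isoform signal in HAX1, TMPO, BSCL2 and ASXL1 was under 10 TPM in the GPS167 library. Several of these events covered a small part of their gene's signal. Isoforms of the HAX1 event were at 10.02, 9.32 and 14.52 TPM against a gene mean of 83.85 TPM over the libraries. Those of ARPP19 were at 10.3, 35.2 and 16.5 TPM against 117 TPM, and those of RPS20 at 11.2, 17.6 and 22.5 TPM against 2935 TPM. Regardless of isoform level, 35 events were tied at a difference of 100 points. The 10 that the rule took from these ties (among them those in EPB41L2, CLTA, CYB5R3, BIN1, GGT1, BDNF, PRRG1 and ZSCAN2) had isoforms of at most 2.68 TPM.

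**Figure D4:**
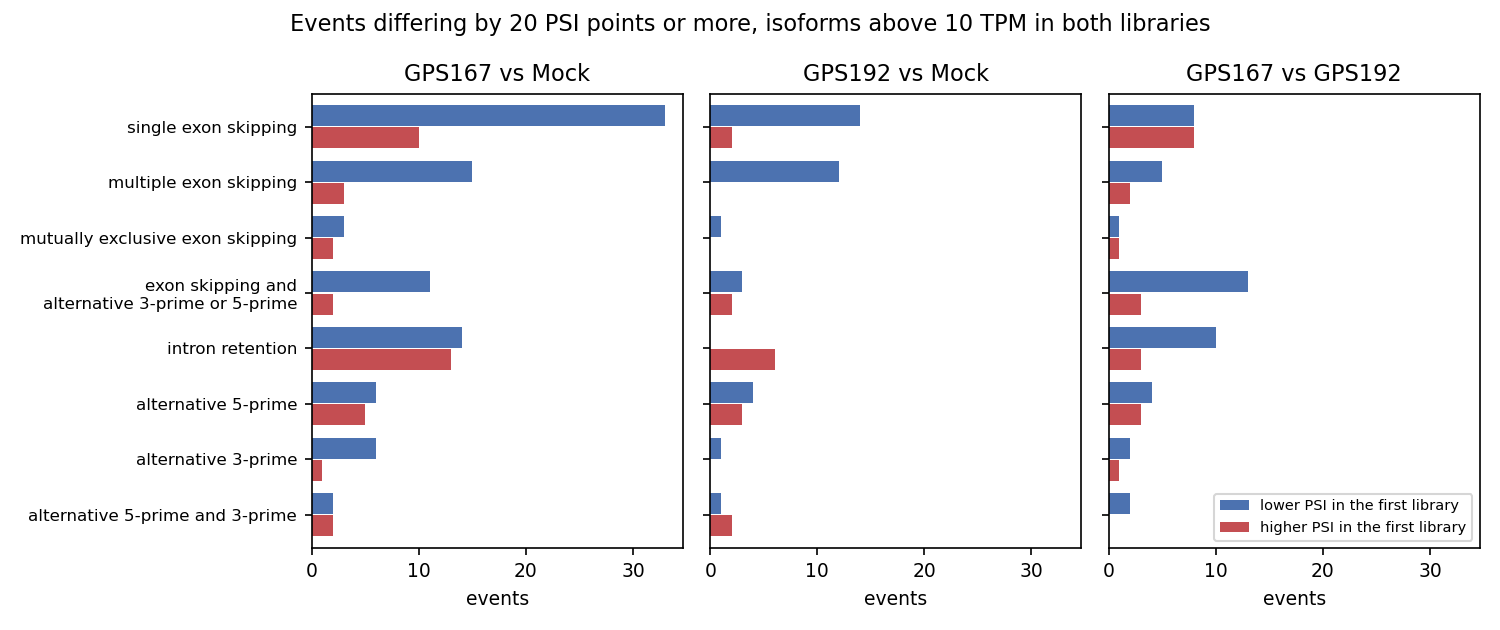
Number of splicing events per class with a PSI at least 20 points higher (red) or lower (blue) in the first library named in each panel, among events with isoforms above 10 TPM in both libraries. Single exon skipping had 33 lower and 10 higher events in GPS167 against Mock, 14 and 2 in GPS192 against Mock, and 8 and 8 in GPS167 against GPS192.

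MDM2 and its relative MDM4, both negative regulators of p53, had differing events in both treated libraries. An MDM2 event that spans 68813629 to 68839622 on chromosome 12 holds 2 alternative coding parts. It was at 33.1% PSI in Mock, 70.4% in GPS167 and 65.4% in GPS192, with isoforms at 16.6, 99.4 and 88.6 TPM. Another MDM2 event, of mutually exclusive exons, went the other way, at 85.9%, 62.0% and 65.8%. Its isoforms were at 38.9, 184 and 170 TPM. The other MDM2 events with isoforms above 10 TPM in all 3 libraries were under 20 points. The furthest apart of these was at 3.13%, 12.4% and 14.4%. A 68-nt coding exon of MDM4 (chromosome 1, 204537430 to 204537497) was included at 96.5%, 64.6% and 70.7%, with isoforms at 12.8, 11.6 and 11.7 TPM. With isoforms above 10 TPM, MDM2 and MDM4 made 2 of 14 p53 regulators past 20 points in GPS167 (percentile 93.2 of random lists) and 2 of 15 in GPS192 (percentile 98.8). In the whole set of events the percentiles were 14.6 and 19.3. Below 20 points, the p53 regulators ING1 and TP53BP1 were at 37.6%, 22.4% and 32.3% and at 72.2%, 57.8% and 75.2%.

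Among the splicing factors, SRSF2 had an intron of 995 nt outside the coding sequence (chromosome 17, 76735159 to 76736153) retained at 58.1% in Mock, 19.5% in GPS167 and 40.6% in GPS192. SF3B1 retained an intron of 1476 nt at 83.9%, 61.3% and 69.6%, a 158-nt coding exon of HNRNPC was at 68.1%, 43.3% and 74.9%, and SNRPD2 was at 38.3%, 18.1% and 38.2%. These percents hold for part of each gene's transcripts. Isoforms of the SF3B1 event were at 57.7, 60.8 and 59.1 TPM against a gene mean of 184.5 TPM. Those of HNRNPC were at 92.4, 67.9 and 43.6 TPM against 1111 TPM, and those of SNRPD2 at 19.1, 66.6 and 25.6 TPM against 780 TPM. CLK1 had an event with a 91-nt coding exon (chromosome 2, 200860125 to 200860215) at 76.4%, 91.8% and 89.8%, under 20 points in each comparison. HIPK3 (10.9%, 28.8% and 23.5%), SRPK1 (14.7%, 26.3% and 18.0%), CLK2 (43.6%, 42.5% and 48.5%), SRSF5 (50.3%, 67.8% and 66.7%), TRA2A (71.8%, 88.3% and 82.3%), PTBP1 (45.9%, 32.0% and 42.3%) and SF1 (40.8%, 27.8% and 33.8%) were also under 20 points. For SRSF10, among events with isoforms above 10 TPM, the one furthest apart in GPS167 against Mock was at 55.6%, 46.6% and 47.7%. In GPS192 against Mock it was another event, at 65.4%, 60.5% and 56.8%. Both were single exon skipping events. Between the compounds it was an alternative 3-prime event, at 55.2%, 48.8% and 57.3%. CDKN1A had no event past 20 points with isoforms above 10 TPM. Its event furthest apart in GPS167 against Mock was at 3.86%, 10.2% and 6.30%.

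Of 13 reported SRSF10 splicing targets with isoforms above 10 TPM, 0 had an event past 20 points in any of the 3 comparisons. Matched random lists gave means of only 0.42 (GPS167 against Mock), 0.22 (GPS192 against Mock) and 0.20 genes (GPS167 against GPS192). A count of 0 therefore does not set this list apart. The members furthest apart were BCLAF1 (a 147-nt coding exon at 50%, 36.7% and 45.5%), AKIP1 (52.4%, 42.6% and 53.4%), NUMB (35.9%, 26.5% and 32.4%) and AURKB (72.3%, 63.2% and 68.1%). Without the isoform limit BRCA1 passed in GPS167 and BRCA1 and FANCA in GPS192. Over all events, 1 of 12 SR protein kinase genes (DYRK1B), 1 of 8 SR genes, 1 of 21 hnRNP genes, 2 of 20 core spliceosome genes, 6 of 29 apoptosis regulators, 5 of 32 repair genes, 2 of 16 p53 regulators and 1 of 16 SRSF10 targets passed 20 points in GPS167. In GPS192 these counts were 0, 0, 0, 0, 5, 6, 2 and 2. The hnRNP shares lay low among random lists, at percentiles 1.25 and 0.225, where 4.52 and 3.97 genes were the random means, but with isoforms above 10 TPM they lay inside the central 95%, at 48.8 and 28.9. The 7 other lists lay inside the central 95% in both comparisons with Mock.

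With isoforms above 10 TPM, of 20 core spliceosome genes, SF3B1 and SNRPD2 passed in GPS167 and 0 in GPS192. SRSF2 was the 1 SR gene of 8, and HNRNPC the 1 hnRNP gene of 20, past 20 points in GPS167, and 0 of each list passed in GPS192. Of the SR protein kinases, 0 of 6 passed in GPS167 and 0 of 7 in GPS192, and of the DNA repair genes 0 of 17 and 0 of 16. Random lists gave means of 0.09 and 0.03 genes for the kinases and 0.37 and 0.16 for the repair genes. Counts of 0 therefore do not set these lists apart. For core spliceosome, SR and hnRNP genes the random means were 0.41, 0.21 and 1.12 in GPS167 and 0.19, 0.08 and 0.52 in GPS192. Among apoptosis regulators 0 of 22 passed in GPS167 and 2 of 23 (FAS and BIRC2) in GPS192, at the upper bound of the central 95% of random lists.

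**Figure D5:**
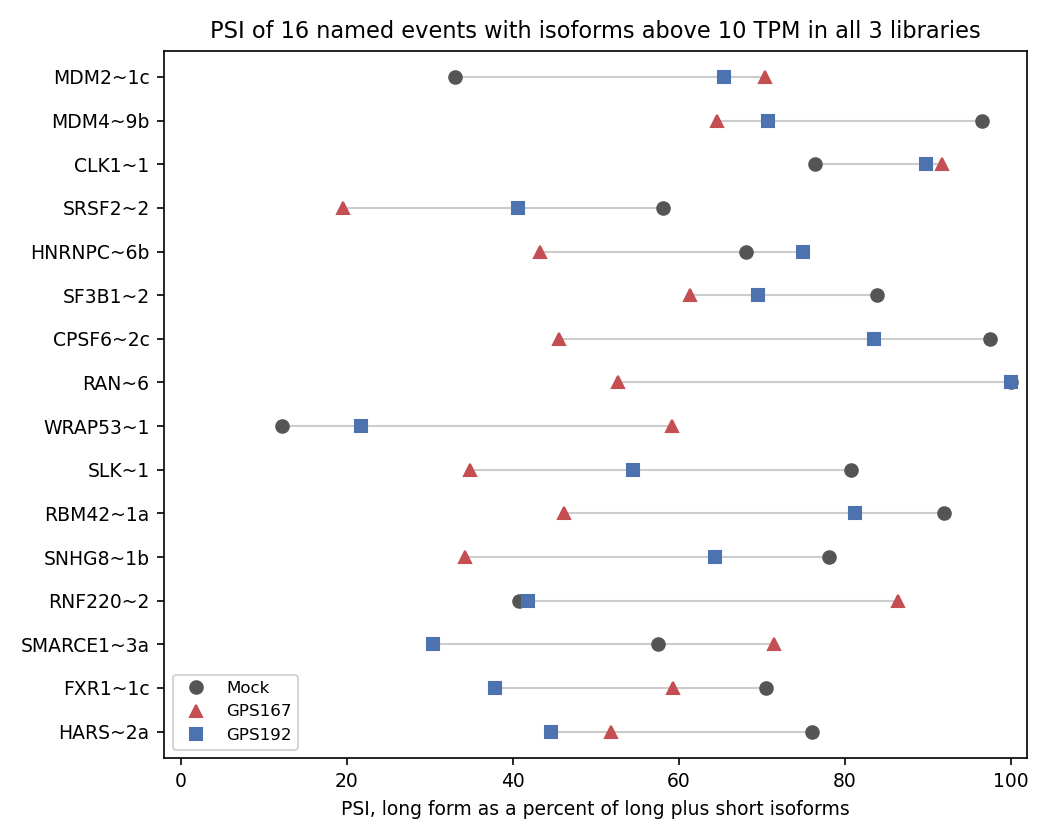
PSI (x axis, percent) of named events with isoforms above 10 TPM in all 3 libraries, 1 point per library. The long form of MDM2~1c was at 33.1% in Mock and at 70.4% and 65.4% in the treated libraries, that of RAN~6 at 52.7% in the GPS167 library alone, and that of SMARCE1~3a at 30.4% in the GPS192 library.

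Between the compounds' libraries, 649 events had a PSI at least 20 points higher and 741 a PSI at least 20 points lower in GPS167, in 877 genes; with isoforms above 10 TPM these were 21 and 45 of 11943, in 50 genes. RAN, CPSF6, WRAP53, RBM42 and RNF220 stood apart here too, with RAN at 52.7% in GPS167 and 100% in GPS192. A 44-nt coding exon of the chromatin remodelling gene SMARCE1 (chromosome 17, 40645576 to 40645619) was at 71.5% and 30.4%, COX7A2 at 57.5% and 23.3%, and CLDND1 at 4.22% and 41.3%. MAGEA2 was at 59.1% and 100%, and the host gene SNHG15 retained an intron at 50.7% and 90.4%. Single exon skipping had 8 events in each direction. Regardless of isoform level, 31 events were tied at a difference of 100 points. The 10 taken from these ties (in HOXB3, CPSF3L, ZNF268, SLC27A5, WDR37, ETV1, BACE1, PDLIM3, CD59 and ASNS) had isoforms of at most 0.95 TPM.

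The PSI differences of both compounds from Mock had a Pearson correlation of 0.55 over 24173 events, against 0.50 (at most 0.53) in simulated unchanged libraries, and a covariance of 81.7 against 66.5. Higher by 20 points in both were 320 events, against 318.7 in the simulation, and lower in both 360, against 319.8 (at most 372). With isoforms above 10 TPM in all 3 libraries, the correlation was 0.62 against 0.50, and 5 events were higher and 12 lower in both, against 7.46 (at most 15) and 7.33 (at most 13) in the simulation. Lower in both were 195 events with a host gene mean of at least 10 TPM (simulated at most 193) and 231 with 1 event per gene (at most 222). The 1 event per gene was the one with the largest difference from Mock in either compound. The simulation did not repeat this choice, so the count of 231 cannot show an excess over it. Part of any excess may again come from the shared Mock library.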

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

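Both compared libraries above 10 TPM, isoforms above 10 TPM, and leaving out short and non-polyadenylated RNA genes were alternatives chosen after the data were seen; the others were fixed before the data were examined.

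Counts of genes at least 2-fold higher and lower were 643 and 296 for GPS167 against Mock, 340 and 120 for GPS192 against Mock, and 205 and 117 for GPS167 against GPS192. They are given below in this order, wherever they differed by more than 1.5 times. A pseudocount of 0.1 gave 531 lower genes, then 604 and 200, then 309 and 282; a pseudocount of 5 gave 279 and 112, 131 and 49, and 96 and 41. A larger pseudocount shrinks the differences of genes at low TPM by construction. A mean of at least 10 TPM, which compared 7984 genes, gave 336 and 146, 166 and 63, and 91 and 27. Both libraries above 10 TPM gave 216 and 103 of 7296 genes, 100 and 43 of 7449, and 70 and 16 of 7628. A threshold of 1.5-fold gave 1922 and 1233, 1285 and 548, and 688 and 676, and 3-fold gave 206 and 49, 104 and 22, and 70 and 38, by construction. Without a filter, under median ratio scaling and without short RNA genes the counts stayed within 1.5 times. More genes were higher than lower under each of these alternatives in each comparison.

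Of 25 list medians per comparison, 14, 15 and 17 lay outside the central 95% of random lists, and these counts stayed within 1.5 times under each alternative tried. Over the single list medians, 357 results kept their direction and side, or lay inside the central 95% both times, while 9 moved outside, 8 moved inside and 1 took the other sign and moved outside. Moved inside, with percentiles, were DNA damage response and repair in GPS167 against Mock (88.3 with a mean of at least 10 TPM, 97.46 without short RNA genes), Wnt targets (78.54 and, unmatched, 97.27), colon differentiation (60.28 with a mean of at least 10 TPM) and, unmatched, core spliceosome genes (97.45) in GPS192 against Mock, and SR protein kinases (97) and hnRNP proteins (97.36) in GPS167 against GPS192, these with a mean of at least 10 TPM. Moved outside were SR protein kinases in GPS167 against Mock (97.88 unmatched, 98.45 with a pseudocount of 0.1, 97.87 with a mean of at least 10 TPM), ribosomal proteins in GPS192 against Mock (0.82 unmatched, 2.21 under median ratio scaling, 2.42 without short RNA genes), Wnt targets in GPS167 against Mock (98.42, mean of at least 10 TPM) and against GPS192 (1.64, pseudocount 0.1), and G2/M genes in GPS167 against GPS192 (99.04, mean of at least 10 TPM). The cause was not tested. The 1 that took the other sign was the interferon list in GPS167 against Mock, whose median was 0.05 and became -0.42, outside the central 95%, with a mean of at least 10 TPM; the cause was not tested. Among the named genes, 1162 results stayed on their side of 2-fold, 37 no longer passed it and 7 newly passed it.

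The correlation of the compounds' expression differences was 0.692; it was 0.734 with a mean of at least 10 TPM and 0.7245 without short RNA genes, whose differences scatter widely.

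Counts of events with higher and lower PSI were 738 and 986, 636 and 774, and 649 and 741 in the same order of comparisons. A difference of 10 points gave 1882 and 2549, 1686 and 2084, and 1770 and 2011; 30 points gave 368 and 499, 340 and 382, and 312 and 390, by construction. No filter on the host gene gave 1343 and 1603, 1280 and 1339, and 1228 and 1393. A host gene mean of at least 10 TPM gave 387 and 556, 311 and 406, and 312 and 371, and 1 event per gene 442 and 568, 363 and 460, and 371 and 407, with fewer events compared. Isoforms above 10 TPM left 38 and 90, 15 and 36, and 21 and 45, since many of the other events had isoforms under 1 TPM. Events with lower PSI outnumbered those with higher PSI under each of these alternatives.

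With isoforms above 10 TPM, the percent of single exon skipping events past 20 points that had lower PSI was 76.7 in GPS167 and 87.5 in GPS192 against Mock, beside 62.3 and 63.4 over all events; the cause was not tested. The correlation of the PSI differences was 0.554. It was 0.589 with a host gene mean of at least 10 TPM and 0.616 with isoforms above 10 TPM, and the cause was not tested. With 1 event per gene it was 0.581, but those events were chosen by the size of their differences from Mock, so this value is not a like comparison. Of 8 splicing lists, 1 (hnRNP proteins) lay outside the central 95% in GPS167 against Mock, but 0 with a host gene mean of at least 10 TPM and 0 with isoforms above 10 TPM; at 10 points the hnRNP list lay inside, at percentile 8.675, and SRSF10 targets outside, at 0.33. In GPS192 against Mock 1 lay outside, hnRNP proteins again, and 2 did at 10 points. With isoforms above 10 TPM the list outside was another, p53 regulators, at 98.8, with hnRNP proteins at 28.9. In GPS167 against GPS192 0 did, and 1 (hnRNP proteins) did at 10 points. The cause was not tested.

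The totals of genes and events kept their larger direction, and no list median outside the central 95% took the other sign. Single classes of events did not all keep it: intron retention had 59 higher and 39 lower events in GPS192 against Mock but 185 and 191 at 10 points, and in GPS167 against Mock 77 and 82, but 180 and 170 without a filter on the host gene and 45 and 44 with a host gene mean of at least 10 TPM. List medians inside the central 95% did take the other sign, among them Wnt targets in GPS167 against GPS192, from -0.22 to 0.19 with a mean of at least 10 TPM, and the lists near 0 named as such in the text; the cause was not tested. Sequencing depth is unknown, so the range of TPM in which counting alone gives differences of this size is not known, and with 1 library per treatment no alternative shows how much a repeat would vary.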

Other observations

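The tests of reads without a poly(A) tail, shared histone reads, replication genes and library scatter below were chosen after the results were seen; those of low values, short transcripts, intron number and loss of mRNA were written before. List results here are values with no explanation. Cholesterol synthesis genes had a median log2 difference of -0.03 in GPS167 and 0.54 in GPS192 against Mock (random range of the latter -0.06 to 0.27), and all 23 were lower in GPS167 than in GPS192, with HMGCS1 at 21.7, 26.6 and 51.7 TPM in Mock, GPS167 and GPS192. Interferon response genes had medians of 0.05 and 0.49, and -0.40 between the compounds. Members went both ways, with ISG15 at 152, 428 and 502 TPM but IFITM1 at 25.7, 3.15 and 11.9 TPM. At least 2-fold higher and lower than in Mock were 3 and 3 members in GPS167, and 6 and 1 in GPS192. With a mean of at least 10 TPM the median in GPS167 was -0.42. ATF4 and stress response genes had medians of -0.30 and -0.37, both below the random lists, with PSAT1 at 218, 87.6 and 70.6 TPM and TRIB3 at 82.7, 34.8 and 27.5 TPM, but ATF3 at 25.6, 186 and 159 TPM.

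Hypoxia genes had medians of -0.25 and 0.11, with BNIP3L at 52.5, 23.0 and 40.1 TPM and ALDOC at 56.7, 25.0 and 46.2 TPM, but ADM at 27.4, 451 and 113 TPM. NRF2 targets had medians of -0.23 and 0.16, with NQO1 at 773, 267 and 594 TPM and SLC7A11 at 29.9, 9.21 and 8.69 TPM, but HMOX1 at 13.4, 42.8 and 35.7 TPM. The medians of these lists between the compounds were -0.37 and -0.27. Wnt targets had medians of 0.06, 0.29 and, between the compounds, -0.22, and with a mean of at least 10 TPM 0.48, 0.18 and 0.19. Colon differentiation genes had medians of -0.04, 0.41 and -0.26, with KRT8 at 964, 1675 and 1981 TPM (under 2-fold in GPS192 with median ratio scaling); with a mean of at least 10 TPM the median in GPS192 was 0.06, inside the central 95%. SnoRNA host genes had medians of 0.57, 0.14 and 0.24, with SNHG1 at 294, 984 and 422 TPM. Cytosolic ribosomal protein genes lay at -0.08, -0.07 and 0.01, the last below 0 without short RNA genes. Mitochondrially encoded mRNAs lay at 0.10, 0.03 and -0.05, the second below 0 under median ratio scaling. Of the fibroblast, leukocyte and endothelial markers 1 gene each was measured, COL1A1, CD68 and EGFL7; the summed TPM of the lists in the 3 libraries was 4.57, 3.03 and 5.17, then 32.9, 46.1 and 40.3, then 51.6, 48.9 and 43.7.

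Histone genes were higher in the GPS167 library. Histone mRNAs mostly lack a poly(A) tail, but 51 other RNA genes without such tails and of at least 200 nt had a median log2 difference from Mock of 0.0681 (bootstrap interval -0.16 to 0.31), which argues against more RNA of this kind in the library. TPM summed over 59 histone genes was 16.8113 times that of Mock (175 and 2948 TPM) and at least 14.2 times when any 1 gene was left out, which argues against reads moved between copies. Replication genes, which are active when histones are made, were higher in GPS167 than in GPS192 by a median of 0.7384, and more cells in S phase may be part of the pattern; but in GPS192 against Mock histone genes were higher too (summed TPM 2.60 times Mock) while replication genes had a median of -0.13. A compound effect and an accident of a single library stay open, untested, since each treatment has 1 library.

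Aryl hydrocarbon receptor targets were higher in the GPS192 library. Their median of -1.6288 in GPS167 against GPS192 is the pattern itself, so it decides nothing on scatter between single libraries, which cannot be told apart from an effect with 1 library per treatment. Of 13559 genes in the list's range of Mock TPM, which is most genes compared, the 90th percentile of the difference of GPS192 from Mock was 0.5435, and of the 5944 at most at 10 TPM in Mock it was 0.611, with a median of 0.10. The list median of 1.45 lay above both, which argues against a general rise of low values, though with a mean of at least 10 TPM it was 0.56. Activation of the receptor by GPS192 or by something else in that culture may lie behind the list, and this stays open, untested.

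RNA genes with transcripts under 200 nt differed widely. The SD of their log2 differences was at least 5.4183 times that of longer genes of like expression in each of the 3 comparisons, and 57.9%, 50% and 65.8% of 38 such genes passed 2-fold, against 6.598%, 3.16% and 2.14% of longer genes. Poor quantification of short transcripts may therefore lie behind RNA5-8S5, SNORA70, SNORA46 and RNVU1-6 among the named genes. A compound effect on these RNAs stays open, untested.

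A hypothesis was that a load on splicing leaves genes with few introns higher. Across 11976 protein-coding genes, exon number and log2 difference had a Spearman correlation of -0.131 in GPS167 and -0.0747 in GPS192 against Mock; the latter lay between the bounds set beforehand (-0.1 and -0.05), so the tables leave it open. A second hypothesis was that genes with a large PSI difference lose mRNA. Only genes with isoforms above 10 TPM in both compared libraries were taken, 106 in GPS167 and 46 in GPS192, against 1063 and 889 over all events. The 106 genes had a median log2 difference of 0.2293, at percentile 99.9 of matched random lists. The 46 had a median of -0.0035, at percentile 4.52, inside the central 95%. Neither lay below the random lists. Genes that lost much mRNA could fall under 10 TPM and drop out, so this cannot decide whether such genes lose mRNA.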
